A study of Homo sapiens with 16 samples.

How the data were processed

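The series holds 16 libraries of polyA RNA from H1299 and HBE cells at passage 15 to 18, with 1 library per group. Per the labels' protocols, H1299 cells were transfected with a Flag-FLII or an empty plasmid with a lipid reagent, HBE cells were stably transduced with short hairpin RNA against FLII, RNC RNA was obtained from cycloheximide-treated lysates by ultracentrifugation through sucrose, and libraries were made with an Illumina mRNA kit. How cytosol and nuclear RNA were separated, the sequencing machine, the aligner and the counting tool are not given in the sources used here. GRCh37 and hg19 are named in the submitters' processing notes. The reference annotation at hand is of another build, so no coordinates are given. Libraries were assigned to groups by their titles.

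Per the file headers, each deposited file gives for 23709 RefSeq genes a length, a read count and an RPKM. The authors' read counts are whole numbers with a different total in each library, with the splice variants of a gene merged into 1 entry. The deposited RPKM equals the read count scaled to the stated length and to the library's own total, as checked on the values. Of the genes, 18646 carry NM and 5063 NR accessions. Some symbols look like calendar dates, as spreadsheet programs write them, and these were not named. Symbols that name no gene, Y-linked genes and XIST were left out of the names. No batch, date or replicate is given in the labels.

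Counts were compared within each pair of libraries of the same line and RNA fraction. The 2 libraries were scaled with TMM (edgeR 4.0.16 in R 4.3.3), 0.5 reads were added to each scaled count, and genes with at least 20 reads over the pair were kept. The 95% interval of a fold is the exact conditional binomial (Clopper-Pearson) interval. A gene was called when its absolute log2 fold was at least 1 and the interval excluded a fold of 1. For the change of RNC over mRNA and of nuclear over cytosol, the 2 log2 folds were subtracted for genes kept in both pairs, with an interval from the inverse counts. No p-values are given, since no group has replicates; PCR duplicates cannot be seen in counts, so intervals and floors cover counting error only. Against a count of 0 the fold is a lower bound against a floor of 3 counts.

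There were 12 comparisons: 8 of a fraction and 4 of a ratio of fractions. In all, 29 gene lists with 938 memberships, of which 935 were found in the files, were fixed before the data were examined. Each list has a median log2 fold and its percentile among 10000 random lists of the same size matched on expression. In all 343 such medians were computed, so some outside the percentiles of 1 and 99 arise by chance. The random lists draw genes independently and are not matched on length or GC content. Lists whose members vary together, such as ribosomal protein genes, can therefore pass these percentiles more readily, and a percentile is not a chance rate. Genes called the same way in several fractions, or opposite ways in the lines, were set against 1000 permutations of the folds within 20 bins of expression. Control libraries shared no reads between fractions.

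The genes named follow a rule fixed before the data were examined. FLII comes first. Then come, by the interval bound nearest 0, the 10 genes in each direction in mRNA and RNC, the 6 in cytosol and nuclear RNA and the 8 in each ratio; genes called alike in all fractions; genes called oppositely in the lines in mRNA or RNC; and up to 4 members of each list set apart. Other members of short lists, CLIC4 and MNX1, the genes of the line contrast and the cytosol gene G2E3 were chosen after their values were seen.

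Line-typical genes were chosen after the data were examined, from mRNA and nuclear libraries alone: genes at 5 CPM or more in one line and 50 times above the other (0.05 CPM added), 180 for H1299 and 199 for HBE, of which 159 and 184 had 5 CPM or more in the control cytosol library of their line. For tests on an mRNA library these genes were chosen again without the mRNA libraries of the other line, which gave 193 for H1299 and 244 for HBE. In 1 alternative, 2551 genes with levels 8 times apart or more between the lines were left out, the line-typical genes among them. A list median in that alternative covers only the members that remain. GC content was taken from the annotation for 95.0% to 96.0% of the genes kept.

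The alternatives fixed before the data were examined were total counts, median of ratios (DESeq2 1.42.0 size factors), no filter beyond 1 read, at least 100 summed reads, 5 reads added, and the deposited RPKM with 1 added and at least 1 RPKM in either library. The fold calls, their intervals, the ratio calls and the list percentiles were tested on simulated data. The permutations, correlations, line-typical levels and removal of the GC trend were not. Counts were drawn with Poisson noise from the real library sizes and from gene means pooled over each pair. In each pair of libraries 200 genes were changed by known folds, so that a ratio carries the changes of both pairs. The changed genes had at least 20 expected reads in the control library, so recovery was not measured for kept genes below that. Over the fraction comparisons, run on 10808 to 14656 genes, 3-fold changes were called for 95% to 100% of genes and 6-fold changes for 100%; over the ratios, run on 10683 to 12383 genes, 94.4% to 97.9% and 98.4% to 100%. Unchanged genes were called 43 to 80 times in a fraction and 67 to 154 times in a ratio; a limit first set on that number was exceeded and was dropped, and the numbers are given instead. Intervals held the true fold for 95.2% to 96.1% of genes. The simulation holds no variation between cultures or library preparations, so these numbers set no rate of false calls for the real libraries. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest.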

Results

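RNA sequencing counts were examined for 16 human libraries from 2 lung cell lines, each with 1 library per group. H1299, a non-small cell lung carcinoma line, had been transfected with an expression vector for Flag-tagged FLII or with the empty vector. HBE, labelled as a lung epithelial line, carried a lentiviral short hairpin RNA against FLII or the control named NC in the labels. FLII (flightless I) is an actin-remodelling protein of the gelsolin family. For each of these groups 4 kinds of RNA were sequenced: mRNA, RNA pelleted with the ribosome-nascent chain complex (RNC, the RNA engaged with ribosomes), cytosolic RNA and nuclear RNA. Reads assigned to genes totalled 5943676 to 8344359 in the mRNA libraries, 26711771 to 38514467 in the RNC libraries, 5914489 to 9259569 in the cytosol libraries and 6295282 to 8201848 in the nuclear libraries. Genes for cytosolic ribosomal proteins took 6.89% to 8.70% of the reads in mRNA, 25.4% to 34.5% in RNC, 15.9% to 18.1% in cytosol and 11.1% to 15.2% in nuclear libraries. With 1 library per group there was no replicate check: each fold compares those libraries, not the conditions, and its 95% interval covers counting error only. A gene was called higher or lower when its fold was at least 2 and the interval excluded a fold of 1. A gene list was described when its median lay under percentile 1 or over percentile 99 of 10000 random lists matched on expression.

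FLII (NM_002018) was examined first in every library, because it checks the labels. In H1299 it was higher in the library labelled FLII overexpression in mRNA (log2 fold 2.14, interval 2.09 to 2.20; 625 against 143 RPKM), cytosol (1.66, 1.59 to 1.72; 210 against 70.1 RPKM) and nuclear RNA (1.86, 1.79 to 1.94; 252 against 67.6 RPKM). In HBE it was lower in the library labelled FLII knockdown in mRNA (−2.58, −2.73 to −2.44), cytosol (−2.94, −3.15 to −2.75) and nuclear RNA (−2.98, −3.13 to −2.83), that is 5.99-fold, 7.68-fold and 7.87-fold lower. The RNC libraries went against this. In the RNC library labelled H1299 FLII overexpression, FLII was 18.5-fold lower than in the RNC library labelled H1299 vector (5.61 against 89.2 RPKM; log2 fold −4.21, −4.30 to −4.11). In the RNC library labelled HBE FLII knockdown it was close to the RNC library labelled HBE NC (log2 fold 0.07, 0.01 to 0.13; 30.0 against 36.5 RPKM), and with total counts in place of TMM scaling that fold was −0.28. FLII therefore did not follow the labels of these RNC libraries, and every direction drawn from them below is a direction between labels.

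**Figure D1:**
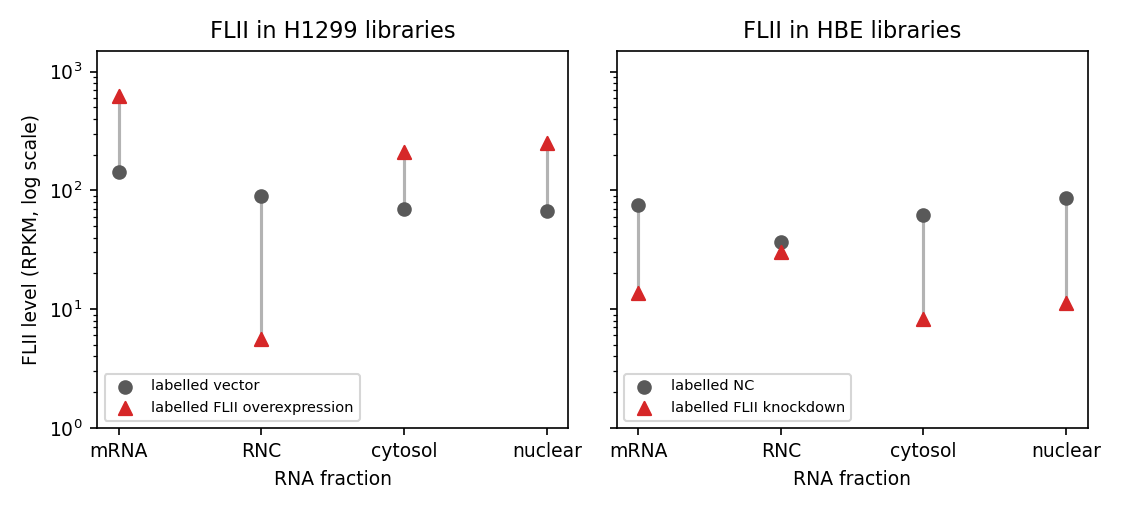
FLII level in RPKM (log axis) in the 16 libraries, by RNA fraction, for H1299 (left) and HBE (right); triangles are the libraries labelled FLII overexpression or FLII knockdown, circles the controls, and a line joins each pair of single libraries. FLII lay at 625 against 143 RPKM in the H1299 mRNA pair and at 5.61 against 89.2 RPKM in the H1299 RNC pair.

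The 2 lines differ strongly in their transcripts, so genes typical of each were followed in all libraries. In mRNA of the controls, the mesenchymal filament gene VIM was higher in H1299 vector than in HBE NC (log2 fold 9.77), while the basal keratins KRT5 (−7.60) and KRT17 (−7.53) and the epithelial cadherin CDH1 (−7.51) were lower; 20 of 25 epithelial markers were lower. Over 159 H1299-typical and 184 HBE-typical genes, the median level was set against the control cytosol library of the same line. In the RNC library labelled H1299 FLII overexpression, H1299-typical genes had a median of 0.672% and HBE-typical genes one of 92.1%. In the RNC library labelled HBE FLII knockdown the values were 42.0% and 1.19%, and in the RNC library labelled H1299 vector 36.3% and 0.369%. The RNC library labelled HBE NC held HBE-typical genes at 43.6% and H1299-typical genes at 3.31%. Among the other H1299 libraries the FLII overexpression cytosol library had the highest median of HBE-typical genes, at 1.94% (quartiles 1.11% and 3.06%) against 0.173% in the vector cytosol library. Next came the vector mRNA library at 0.711%, against 0.251% in the FLII overexpression mRNA library.

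**Figure D2:**
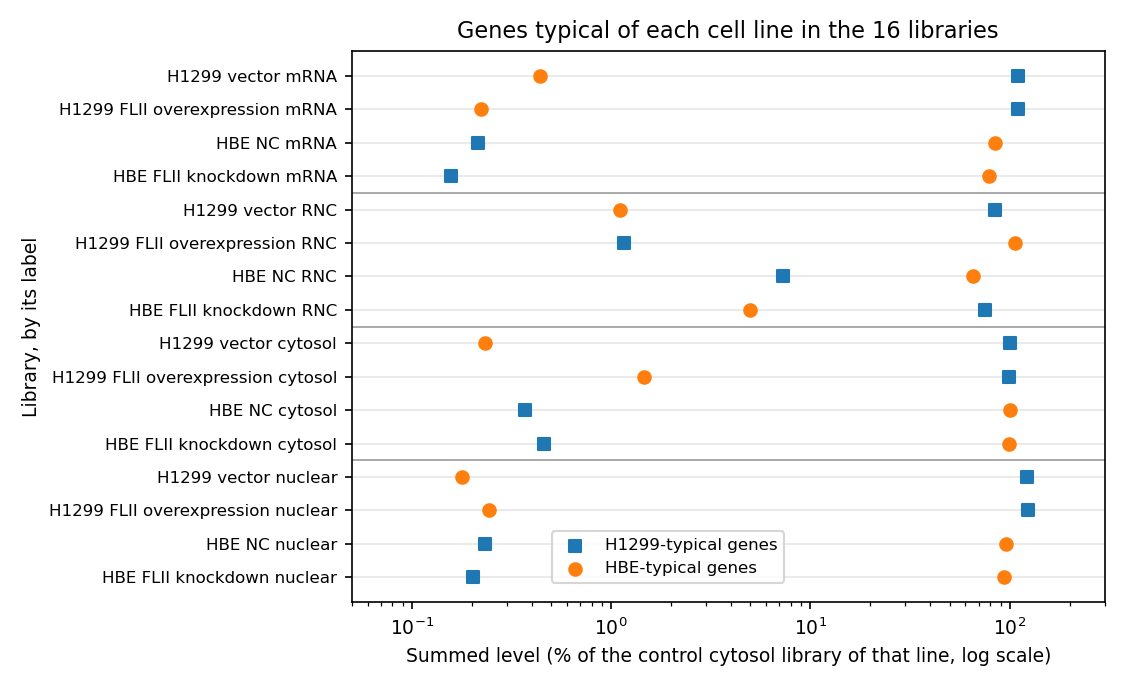
Summed level of H1299-typical genes (squares) and HBE-typical genes (circles) in each of the 16 libraries, as a percentage of the control cytosol library of that line (log axis). The RNC library labelled H1299 FLII overexpression had H1299-typical genes at 1.16% and HBE-typical genes at 106%, and the RNC library labelled HBE FLII knockdown had 74.9% and 4.99%.

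The control libraries also show what the fractions hold. The list named for nuclear-retained RNAs also holds RNAs without a clear shift to the nucleus, such as GAS5 (nuclear over cytosol 0.16 in H1299 vector, −0.05 in HBE NC). The list as a whole was not set apart between nuclear and cytosolic RNA, and with such mixed members it says little about how well these were separated. Its median log2 fold was 0.43 in H1299 vector (percentile 93.2; 4 higher and 2 lower of 14) and −0.05 in HBE NC (percentile 33.1; 5 higher and 3 lower of 13). Of its members, MALAT1 and NEAT1 were higher in nuclear RNA, with log2 folds of 3.35 and 2.56 in H1299 vector and 3.87 and 2.28 in HBE NC. The highest list median in nuclear over cytosol was that of adhesion and extracellular matrix genes. They were higher for 24 of 29 in H1299 vector (1.73, percentile 100) and for 21 of 32 in HBE NC (2.55, percentile 100). Whether the nuclear libraries hold nuclear RNA alone was not tested. The ribosomal protein transcript RPLP0 in the RNC library labelled HBE NC was higher than in the mRNA library (3.58), as were 61 of 74 ribosomal protein genes. VIM, with 49 reads in the HBE NC mRNA library, had 14888 reads in that RNC library. The HBE NC cytosol and nuclear libraries had 18 and 15 reads of it. At 435 CPM it also stood above the 147 CPM in the RNC library labelled H1299 vector. Where these VIM reads came from was not tested, so they show no trait of ribosome-bound RNA in HBE cells.

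The H1299 mRNA comparison asks which transcripts differ in abundance when FLII is overexpressed. Few did: 43 genes were higher and 61 lower of 13033. Besides FLII, the neutrophil chemokine CXCL2 was higher at depth (log2 fold 1.14, 1.03 to 1.25; 2638 against 863 reads), and GPR132 (2.93), SH3BGR (1.73), CATSPERG (2.54) and GRASP (2.47) were higher on 52 reads or fewer in the overexpression library. HERC2P9 (1.52), CHEK2P2 (2.18), GOLGA8I (2.00) and SPRNP1 (1.87) were also higher, but pseudogenes and members of duplicated families can share reads with their copies. Lower genes included the keratins KRT17 (−1.73, −2.24 to −1.27) and KRT81 (−1.43), the mucosal glycoprotein DMBT1 (−1.59), the imprinted RNA H19 (−1.27), IFI16 (−1.96), IGFBP7 (−1.70), ZNF540 (−1.83), HIST4H4 (−2.11) and GAGE12I (−2.11), a member of a family of near-identical cancer-testis genes.

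By group, 4 of 17 epithelial markers were lower in H1299 mRNA and none higher, with a median of −0.20 at percentile 0.195; among these were KRT17, KRT5 (−1.49) and KRT19 (−1.40). KRT5 and KRT19 had 11 and 7 reads in the overexpression library. HBE-typical genes as a whole lay lower in the same pair, with a median of −0.98 over 36 genes, and stood higher in the vector library than in its partner (0.711% against 0.251%). Of 17 replication-dependent histone genes, 1 was lower (HIST1H2BG, 17 against 25 reads) and the median was −0.29 at percentile 0.04. Interferon response genes had a median of 0.12 (percentile 99.97), hypoxia and glycolysis genes −0.07 (0.08), cell cycle genes −0.04 (0.45), nuclear-encoded oxidative phosphorylation genes −0.04 (0.01) and ribosomal protein genes −0.04 (0), with no member called in any of these. In libraries simulated with counting error alone, 45 of 12824 genes given no change were called, against the 104 calls here. With at least 100 summed reads 2 genes were higher and 2 lower.

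The cytosol and nuclear comparisons ask about transcript levels in the RNA labelled cytosol and in that labelled nuclear, whose separation is not described in the sources. In H1299 cytosol 130 genes were higher and 206 lower of 12527. Higher genes included KRT5 (4.42, 3.58 to 5.59), KRT17 (4.00, 3.57 to 4.51), KRT81 (3.68), H19 (3.91), TRIM29 (5.13, 3.24 to 11.16; 36 against 1 reads) and the matricellular gene SMOC1 (33 against 0 reads, at least 17.2-fold higher against a floor of 3 counts). Lower genes included PAPD4 (−1.67), a cytoplasmic poly(A) polymerase, SEC24D (−2.30), a coat protein of endoplasmic reticulum export, the splicing factor CWC22 (−2.19), HMGN5 (−2.48), ANKS1B (−1.26) and the pseudogene TMED10P1 (−3.31, 1 against 21 reads, −9.12 to −1.11).

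Of 19 epithelial markers, 10 were higher in H1299 cytosol and none lower (median 1.06, percentile 100), among them KRT5, KRT17 and KRT19 (3.58). Of 30 adhesion and extracellular matrix genes, 7 were higher (median 0.37, percentile 100), among them COL4A2 (4.43, 2.47 to 10.47; 22 against 1 reads), TIMP3 (4.29, 2.32 to 10.34; 20 against 1) and LAMA3 (2.35). HBE-typical genes stood at 1.94% of their HBE level in this library, and 55 of the 130 higher genes were HBE-typical. No member was called among ribosomal protein genes (median 0.16, percentile 99.08), spliceosome genes (−0.02, 0.41), actin cytoskeleton genes (−0.04, 0.01), cell cycle genes (−0.13, 0.13), NRF2 and redox genes (−0.12, 0.375), proteasome genes (−0.14, 0) or oxidative phosphorylation genes (0.03, 0.58, a median that turned to −0.04 with total counts or RPKM). Folds followed GC content across genes (Spearman 0.53; genes are not independent replicates): median GC was 57.5% in higher genes and 39.9% in lower genes, and with that trend removed, over the 11941 genes with a GC value, 143 genes were higher and 61 lower, against 123 and 189 of these genes before. Without genes that differ 8-fold or more between the lines, 34 genes were higher; with at least 100 summed reads 28 were higher and 39 lower, and with deposited RPKM 59.3% of the calls were higher against 38.7%.

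In H1299 nuclear RNA, 53 genes were higher and 25 lower of 13031. Folds fell with GC content across genes (Spearman −0.26), with a median GC of 44.1% in higher and 51.5% in lower genes. Removal of this trend was not run for this pair. After FLII the higher genes included CES5A (1.15), the agouti signalling gene ASIP (2.05), LRRC1 (1.30) and the organic anion transporter SLCO4C1 (1.57). Lower genes were LINC00265 (−1.69), B3GNTL1 (−1.20), DSCR6 (−1.89), TYW1B (−1.72), LOC728024 (−1.94) and HSD17B13 (−1.81), all on 28 reads or fewer in the overexpression library. Interferon response genes had a median of 0.13 (percentile 99.98), adhesion and matrix genes 0.07 (99.89), ribosomal protein genes −0.10 (0.8) and actin cytoskeleton genes −0.00 (99.48), the last turning positive under the other scalings; none had a called member. In simulation with counting error alone 63 of 12805 genes given no change were called, against 78 calls here. With at least 100 summed reads 4 genes were higher and 0 lower. With deposited RPKM the calls were split 50% higher, against 67.9%.

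The change of nuclear over cytosolic level asks whether transcripts shift between the RNA labelled nuclear and that labelled cytosol. In H1299, 512 genes were higher in this ratio and 123 lower of 12202; with at least 100 summed reads these were 188 and 14, with 5 reads added 319 and 71, and with deposited RPKM 189 and 70. Those higher included PAPD4 (2.49), ANKS1B (1.97), AKAP11 (2.59), the splicing regulator PTBP1 (1.36, 1.33 to 1.39), the actin capping gene CAPZA2 (1.68), KCTD18 (3.43), HMGN5 (2.88) and LYPLA1 (1.59). Those lower included H19 (−4.20), KRT81 (−3.00), KRT17 (−3.09), TUBA4A (−3.50), RNA5-8S5 (−2.50), PTGES (−2.61), the aquaporin AQP3 (−3.37) and UPK3B (−3.25). Epithelial markers were lower for 5 of 14 (median −0.31, percentile 0.28; KRT17, SFN −2.27, DSP −1.83, CLDN4 −1.71) and adhesion and matrix genes for 4 of 28 (−0.32, 0; LAMA3 −1.73). The fall of KRT17 came from the cytosol pair (4.00, against 0.92 in nuclear RNA), whose overexpression library held HBE-typical transcripts, and without genes that differ between the lines the epithelial median was 0.0145. Heat shock genes were higher for 2 of 17 (0.16, 99.71; DNAJB4 1.45, CHORDC1 1.04). No member was called among ribosomal protein (−0.25, 0.315), NF-kB (−0.25, 0.82), actin (−0.02, 99.865) and proteasome genes (−0.01, 99.59), the last 2 turning positive with total counts or RPKM. The ratio fell with GC content (Spearman −0.53), and total counts moved its median over all genes from 0.03 to 0.14.

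The HBE mRNA comparison asks the same question for FLII knockdown. Here 255 genes were higher and 370 lower of 12635. Folds fell with GC content across genes (Spearman −0.26), with a median GC of 49.1% in higher and 55.9% in lower genes. Removal of this trend was not run for this pair. Lower genes included known targets of the hypoxia response: carbonic anhydrase CA9 (−4.43, −4.63 to −4.23; 216 against 4692 reads), NDRG1 (−4.25, −4.36 to −4.14), the prolyl hydroxylase EGLN3 (−3.80) and ANGPTL4 (−4.11). CASP14, a caspase of keratinocyte differentiation, fell by 6.46 (3 against 310 reads, −8.97 to −5.12), and the airway secretory gene BPIFA1 (−4.81, 2 against 70 reads, −8.19 to −3.21), the mucin MUC2 (−2.92), the growth factor PGF (−3.62), PPFIA4 (−4.02) and LOC154761 (−3.67) were lower. Higher genes were led by fibronectin FN1 (4.53, 4.36 to 4.72; 6050 against 263 reads), the microfibril gene MFAP5 (2.88), the smooth muscle actin-binding gene TAGLN (3.24), the cadherins CDH2 (2.37) and CDH11 (2.55), the cytokine IL11 (2.23, 2.11 to 2.35), the lipase LIPG (2.05), IGFN1 (4.09), UPK1B (3.11) and KIAA0319 (3.94, 53 against 3 reads, 2.53 to 6.48).

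Of 29 hypoxia and glycolysis genes, 13 were lower in HBE mRNA and none higher (median −0.85, percentile 0); besides CA9, NDRG1 and EGLN3 they included BNIP3 (−1.98), ADM (−1.96), SLC2A3 (−1.85) and PGK1 (−1.04). In cytosol and nuclear RNA none of the 13 was called: PGK1 had 0.02 in both. Short of the rule for size, some intervals excluded no change: NDRG1 was lower in cytosol (−0.92, −1.11 to −0.73) and nuclear RNA (−0.68, −0.85 to −0.52), BNIP3 in cytosol (−0.37) and CA9 in nuclear RNA (−0.24), and ENO2 was higher in both (0.48, 0.12 to 0.85; 0.51, 0.18 to 0.85). Of 21 NF-kB and inflammatory genes, 7 were lower and 2 higher (median −0.71, percentile 0): CXCL1 (−1.49), RELB (−1.41) and IL8 (−1.39) fell, CCL5 (1.48) rose. Ribosomal protein genes had a median of −0.42 (percentile 0) with no member of 73 called. Cholesterol and fatty acid synthesis genes were higher for 2 of 32 (0.43, 100; INSIG1 1.21, HMGCS1 1.10), and cell cycle genes for 2 of 38 (0.37, 100; CCNE2 1.24, RRM2 1.12). Among immediate early genes NR4A3 (1.46), KLF2 (1.31) and NR4A2 (1.01) were higher of 28 although the list median was −0.26 (percentile 0.55). Oestrogen and nuclear receptor targets had 1 higher (GREB1, 1.41) and 2 lower (ANGPTL4, and the cholesterol exporter ABCA1, −1.42) of 17, with a median of −0.33 (0.21). Heat shock genes (0.12, 99.02) and proteasome genes (0.16, 99.94) had no called member. With at least 100 summed reads 107 genes were higher and 199 lower. Total counts moved the median of all genes from 0.01 to 0.14 and the share of higher genes among the calls from 40.8% to 57.9%.

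**Figure D3:**
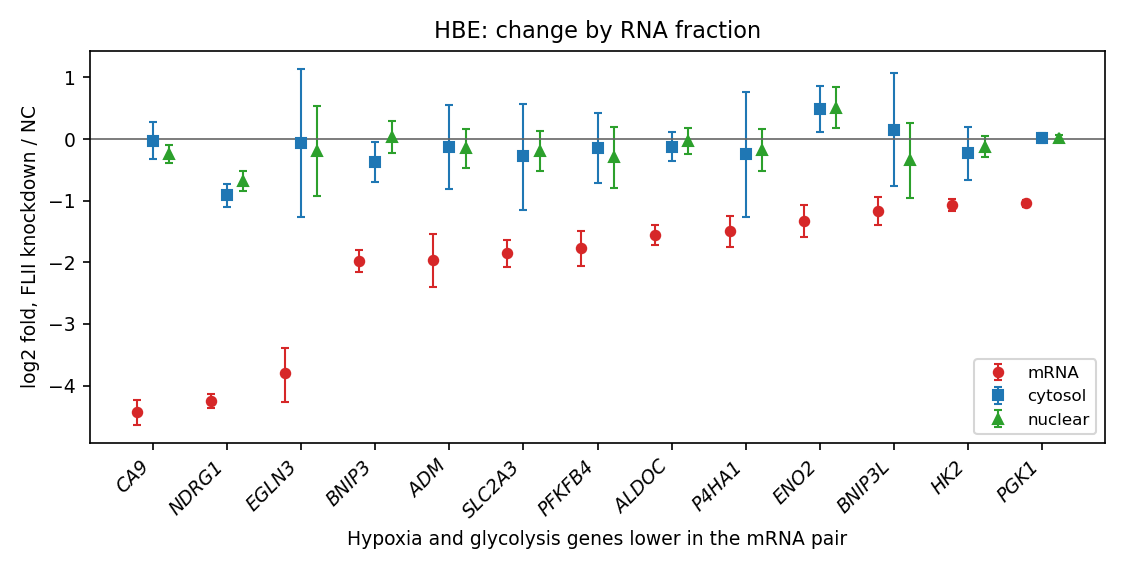
Log2 fold of FLII knockdown over NC in HBE for the 13 hypoxia and glycolysis genes called lower in mRNA, in the mRNA, cytosol and nuclear pairs; points are single pairs of libraries and bars are 95% counting intervals. CA9 lay at −4.43 in mRNA, −0.03 in cytosol and −0.24 in nuclear RNA.

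In HBE cytosol 68 genes were higher and 68 lower of 10884. After FLII, the lower genes included C14orf1 (−1.70, −2.10 to −1.32), BPIFA1 (−2.15), the homeobox gene MNX1 (−1.41), the calcium-binding gene S100P (−1.11) and the muscle enolase ENO3 (−1.25). Higher genes were FSD1 (2.22), WBSCR28 (3.20, 25 against 2 reads, 1.47 to 6.60), LOC440288 (2.95, 21 against 2 reads, 1.19 to 6.36), FAM131B (2.29), the receptor phosphatase PTPRM (2.25) and the ubiquitin ligase G2E3 (2.25). Interferon response genes had a median of 0.22 (percentile 99.97) and 1 of 24 was higher, HERC6 (1.59). Ribosomal protein (−0.11, 0), translation factor (−0.07, 0.24) and spliceosome genes (−0.09, 0.05) had no called member. In simulation with counting error alone 80 of 10608 genes given no change were called, against 136 calls here. With at least 100 summed reads 1 gene was higher and 8 lower (11.1% higher against 50%).

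In HBE nuclear RNA 68 genes were higher and 40 lower of 12368. The globin genes HBB (−4.68, 3 against 79 reads, −7.22 to −3.31) and HBE1 (−3.46, 2 against 24 reads, −6.90 to −1.77) were lower, as were BPIFA1 (−2.74), the trefoil gene TFF1 (−2.57) and C14orf1 (−1.47). The adhesion molecule L1CAM (1.64, 1.13 to 2.20), FSD1 (1.99), PRRT3 (1.55), the ISG15-conjugating enzyme UBE2L6 (1.40), DMBT1 (1.01) and FN1 (1.04) were higher. FN1 was also the 1 higher member of 32 adhesion and matrix genes (median 0.16, percentile 100). No member was called among interferon response (0.15, 99.74), NF-kB (−0.14, 0.27), Wnt target (−0.24, 0.11), ribosomal protein (−0.09, 0) and proteasome genes (0.05, 99.715). In simulation with counting error alone 46 of 12165 genes given no change were called, against 108 calls here. With at least 100 summed reads 5 genes were higher and 9 lower, and with deposited RPKM 42.8% of the calls were higher against 63.0%.

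The nuclear over cytosol ratio in HBE had 82 genes higher and 49 lower of 10776. The apoptosis regulator BCL2 (2.40), ATF7IP (1.54), the centriole gene STIL (1.30), the potassium channel KCNJ15 (1.84), PDPR (1.49), TUSC3 (1.18), C12orf5 (1.01) and C10orf137 (1.66) were higher. G2E3 (−2.86), LOC440288 (−3.06), CCDC157 (−2.09), HEATR1 (−1.66), LRRC10 (−1.44), RNF24 (−1.85), C10orf95 (−1.48) and PTPRM (−2.23) were lower. Spliceosome (0.04, percentile 99.725) and proteasome genes (0.08, 99.98) had no called member. Among 10302 genes simulated with counting error alone and no change in either pair 112 were called, a number close to the 131 calls here. With at least 100 summed reads 2 genes were higher and 0 lower, and with deposited RPKM 47.6% of the calls were higher against 62.6%.

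The RNC comparisons ask which transcripts change in ribosome-bound RNA. Between the libraries labelled H1299 FLII overexpression and H1299 vector, in which FLII went against the label, 3696 genes were higher and 3260 lower of 14187. On the higher side stood KRT17 (12.78; 153930 against 18 reads), TRIM29 (14482 against 0 reads, at least 4059-fold), LY6D (12983 against 0, at least 3639-fold), KRT5 (9515 against 0, at least 2667-fold), FXYD3 (11.52), S100A9 (12.18), MT1E (12.07), PRDX2 (12.06) and H19 (11.29). The lower side held cancer-testis genes, CTAG1A (−13.28), CTAG2 (−13.14; 2 against 19332 reads, −16.53 to −11.64), GAGE1 (−13.17), GAGE8 (−11.56) and GAGE12E (0 against 17869 reads, at least 7084-fold), families whose near-identical copies share reads. The tumour suppressor CDKN2A (−12.03; 3 against 12439 reads, −14.55 to −10.72), H2AFB1 (−13.04; 1 against 10923 reads, −18.97 to −11.19), HBQ1 (−12.65; 1 against 8366, −18.58 to −10.80), FTCD (−12.23; 1 against 6237, −18.16 to −10.38) and ZNF781 (0 against 5453, at least 2162-fold) were lower too. Epithelial markers were higher for 20 and lower for 2 of 25 (median 4.57, percentile 100), endothelial markers higher for 3 of 5 (2.77, 99.66, turning to −0.11 with no filter; PECAM1 2.78, VWF 2.77), and histone genes lower for 14 and higher for 1 of 24 (−1.23, 0.08; HIST1H3D −3.51, HIST1H2AE −2.81). Without the genes that differ between the lines the epithelial median was −0.22, but that setting takes line-typical markers out of the list by construction. Total counts moved the median of all genes from 0.06 to 0.27, and with deposited RPKM 67.0% of the calls were higher against 53.1%.

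Between the RNC libraries labelled HBE FLII knockdown and HBE NC, where FLII did not follow the label either, 2775 genes were higher and 1721 lower of 14703. The directions were those of the H1299 labels turned round: GAGE8 (13.47; 11344 against 1 reads, 11.70 to 19.48), GAGE1 (11.05), GAGE4 (10.73), GAGE5 (10.53), GAGE12E (11.75), CTAG1A (11.04), CDKN2A (12.01; 6665 against 2 reads, 10.56 to 15.46), H2AFB1 (10.81), the embryonic myosin light chain MYL4 (11.32) and ZNF781 (5640 against 0, at least 3077-fold) were higher. KRT5 (−11.62; 1 against 7165 reads, −17.40 to −9.62), KRT17 (−8.63), CLDN7 (−9.06), LY6D (−9.29), FXYD3 (−9.23), the protease inhibitor SLPI (−9.51), the peroxidases GPX1 (−8.59) and PRDX2 (−8.67), RPL29P2 (−8.71) and CBLC (0 against 3282 reads, at least 668-fold) were lower. Epithelial markers were lower for 17 and higher for 1 of 25 (median −1.64, percentile 0), a median that turned to 0.0795 without the genes that differ between the lines. Histone genes were higher for 11 and lower for 1 of 23 (0.89, 99.82; HIST1H3D 2.74), and KRAB zinc finger genes higher for 19 and lower for 2 of 56 (0.57, 99.74; ZNF184 2.49). Lists with low medians had members both ways: NF-kB genes had 7 higher (CXCL2 7.84) and 9 lower (IL1A −5.54) of 24 (−0.65, 0.17; 0.0752 without line-differing genes), stress response genes 7 higher (CHAC1 3.41, DDIT3 2.83) and 3 lower (DDIT4 −2.51) of 29 (−0.54, 0.26), and NRF2 and redox genes 1 higher (OSGIN1 2.40) and 6 lower (FTH1 −2.04) of 26 (−0.68, 0). Adhesion and matrix genes had 4 higher (PLAUR 2.01) and 4 lower (TIMP3 −3.72) of 37 (−0.49, 0.39). Spliceosome genes had 3 higher (SNRPC 1.79) and 1 lower (HNRNPC −1.08) of 41 (−0.37, 0.815), ribosomal protein genes 9 higher (RPS19 1.86) and 10 lower (RPL37 −1.83) of 74 (−0.17, 0.01), and mesenchymal markers 1 higher (TWIST1 1.86) and 3 lower (THY1 −1.22) of 15 (−0.72, 0.26). Total counts moved the median of all genes from −0.09 to −0.44 and the share of higher genes among the calls from 61.7% to 37.7%; with deposited RPKM it was 47.5%.

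The ratio of RNC to mRNA is meant as a measure of translation, but it depends on the same RNC labels. H1299-typical genes stood at a median of 0.672% against 36.3% between the H1299 RNC labels. Between the HBE RNC labels they stood at 42.0% against 3.31%. In the H1299 mRNA pair they stood at 116% and 110%. The ratios below therefore carry the difference between the lines and cannot be read as changes of translation. Between the H1299 labels 2754 genes were higher in this ratio and 2920 lower of 12426. KRT17 (14.51), H19 (12.56), KRT5 (15.58), the protease ST14 (13.98), PRDX2 (12.79), TINAGL1 (12.95) and PTGES (10.89) were higher, and CTAG1A (−13.43), CTAG2 (−13.32), GAGE1 (−13.28), GAGE8 (−11.83), GAGE12E (−15.21), H2AFB1 (−12.89), CDKN2A (−12.06) and HBQ1 (−12.57) lower. These ratio estimates rest on 6 or fewer reads in 1 of the RNC libraries for KRT5, ST14, PRDX2, TINAGL1, GAGE12E, CTAG2, H2AFB1, CDKN2A and HBQ1, so they depend on the reads added and give no bound. Epithelial markers were higher for 12 and lower for 2 of 17 (median 2.77, percentile 100), and their median was −0.28 without the genes that differ between the lines. Oxidative phosphorylation genes were higher for 23 and lower for 10 of 66 (0.41, 99.08; ATP5C1 3.03, COX5A 2.58), hypoxia and glycolysis genes higher for 10 and lower for 3 of 26 (0.74, 99.1; NDRG1 4.26, LDHA 2.80), and interferon genes higher for 7 (IFITM2 5.52) and lower for 15 (IRF7 −8.41, ISG15 −5.05) of 32 (−0.88, 0.11). Total counts moved the median of all genes from −0.03 to 0.20 and the share of higher genes from 48.5% to 58.8%, and RPKM gave 63.1%.

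Between the HBE labels 1862 genes were higher in RNC over mRNA and 1823 lower of 12395. CXCL2 (7.94), EFEMP2 (7.57), FAM171A2 (6.76), ICAM5 (7.13), the interferon-induced IFI6 (6.03) and ISG15 (5.58), the NF-kB subunit RELB (5.75) and LOC284412 (5.38) were higher. KRT5 (−11.59), GPX1 (−8.79), KRT17 (−8.89), FXYD3 (−8.35), SLPI (−8.87), PRDX2 (−8.45), CLDN7 (−8.63) and LY6D (−8.78) were lower; KRT5 rests on 1 read in the RNC library labelled HBE FLII knockdown and SLPI, CLDN7 and LY6D on 10 or fewer, so these estimates depend on the reads added. Epithelial markers were lower for 15 and higher for 1 of 25 (median −1.31, percentile 0; 0.0702 without line-differing genes), adhesion and matrix genes lower for 10 (FN1 −5.26) and higher for 3 of 31 (−0.65, 0.18), p53 targets lower for 10 (PHLDA3 −3.24) and higher for 2 of 24 (−0.66, 0.85), and cell cycle genes lower for 10 (MCM6 −1.58) and higher for 3 (CDT1 2.23) of 38 (−0.78, 0.01). Cholesterol synthesis genes were lower for 10 (IDI1 −1.63) and higher for 2 (MVD 1.40) of 32 (−0.63, 0.39), NRF2 and redox genes lower for 7 (GPX2 −2.24) and higher for 3 of 25 (−0.77, 0.09), and heat shock genes lower for 3 (HSPB8 −2.44) of 17 (−0.72, 0.63). Mesenchymal markers were lower for 5 (CDH2 −2.80) of 8 (−1.14, 0.26), where the RNC library labelled HBE NC, the reference, itself had 12 of 15 of them above its mRNA library (median 4.79, percentile 100), and endothelial markers for 2 (VWF −2.07) of 3 (−2.07, 0.815). Hypoxia and glycolysis genes were higher for 10 (PFKFB4 2.94) and lower for 4 (ALDOC −3.64, CA9 −2.67) of 29 (0.79, 99.885), and immediate early genes higher for 8 (FOSL1 3.42) and lower for 7 (IER3 −1.98) of 28 (0.52, 99.33). Total counts moved the median of all genes from −0.17 to −0.65 and the share of higher genes from 50.5% to 20.9%, and RPKM gave 27.2%.

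Genes called the same way in several fractions were counted against permutations among genes of like expression. In HBE 4 genes were called the same way in all 4 fractions, where 0.014 higher and 0.002 lower were expected. The RNC pair holds a contrast of line-typical genes, so its calls cannot be taken as calls of the knockdown. The 2 higher genes became 1 with 5 reads added and 0 with RPKM or at least 100 summed reads; the 2 lower became 1 with at least 100 summed reads and 0 without genes that differ between the lines. PRRT3 (1.43 in mRNA, 2.10 in RNC, 1.22 in cytosol, 1.55 in nuclear RNA) and VILL, a villin-like relative of FLII in the gelsolin family (1.12, 1.67, 1.63, 1.44; 22 against 6 reads in cytosol), were higher. BPIFA1 (0 against 26 reads in RNC, at least 5.30-fold lower) and S100P (−2.24, −5.66, −1.11, −1.30) were lower. Leaving out the RNC libraries, whose labels FLII did not follow, 5 genes were lower, FLII among them. The others were BPIFA1, S100P, MNX1 (−1.20 in mRNA, −1.10 in nuclear RNA) and the chloride channel gene CLIC4 (−1.77, −1.30, −1.15). The higher genes were again PRRT3 and VILL. By permutation 0.076 higher and 0.014 lower were expected in these fractions. In H1299 no gene was called the same way in 4 fractions, and FLII alone was in mRNA, cytosol and nuclear RNA together. Among the FLII relatives and partners no comparison set the list apart; in HBE mRNA 2 of 16 members were higher, VILL and SVIL (1.13). Across genes, Pearson correlations of folds between fractions ran from −0.15 to 0.21 in H1299 and from 0.01 to 0.26 in HBE.

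The design sets overexpression in one line against knockdown in the other, so genes changed in opposite ways were counted. In mRNA 3 genes went opposite ways, against 2.20 expected by permutation: FLII, DMBT1 (−1.59 in H1299, 1.57 in HBE) and DLEU1 (26 against 38 reads in H1299, 1.05 in HBE), while 5 genes went the same way; the correlation across 11553 genes was 0.03. In cytosol FLII and G2E3 went opposite ways (2.00 expected) and in nuclear RNA FLII alone (0.413 expected). In RNC, 3413 genes went opposite ways between the labels against 1060 expected, and 19 the same way, with a correlation of −0.88 across genes. Examples were KRT5, RAC2, KLK9 and SLPI (10.05 in H1299, −9.51 in HBE) on one side and MYL4 (−11.09 and 11.32), CDKN2A and ZNF781 on the other. Both pairs of RNC libraries hold a contrast of line-typical genes, at 0.672% against 36.3% for H1299-typical genes between the H1299 labels and 42.0% against 3.31% between the HBE labels.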

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

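All tests of explanations in this part were chosen after the results were seen, and so were the gene sets typical of a cell line. The results that follow were set aside because H1299 and HBE, or single fractions of them, moved in opposite directions; with 1 library per group the difference was not tested.

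FLII moved in opposite ways in the lines in mRNA, cytosol and nuclear RNA, with log2 folds of 2.14, 1.66 and 1.86 in H1299 against lower levels in HBE, and in RNC it was at −4.21 in H1299; the difference was not tested. Ribosomal protein genes had medians of −0.0368 in H1299 mRNA, 0.16 in cytosol and −0.10 in nuclear RNA, so the fractions of 1 line went apart; the difference was not tested. Epithelial markers had medians of −0.20 in H1299 mRNA, 4.57 in RNC and 1.06 in cytosol; the difference was not tested. Adhesion and extracellular matrix genes had medians of −0.49 in HBE RNC and 0.16 in HBE nuclear RNA; the difference was not tested.

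In the RNC libraries, the first pattern weighed, the library labelled H1299 FLII overexpression held genes typical of H1299 at a median of 0.672% of their vector cytosol level, which no change of FLII within H1299 would leave, so the tables argue against FLII alteration in the labelled line. The HBE-typical genes had a median of 92.1%, in line with a wrong cell line label on this library. An exchange of the labels with the RNC library labelled HBE FLII knockdown alone is not borne out in full. FLII in that library was at −2.20 against the RNC library labelled H1299 vector, where overexpression would put it above. In the library labelled H1299 FLII overexpression it was at −2.12 against HBE NC, the sign of a knockdown. An exchange among 3 labels, the H1299 vector label included, has both signs. It was framed after these FLII levels were seen, so they give it no separate support. Both ratios may be affected by other RNA in these libraries. HBE NC held H1299-typical genes at a median of 3.31% (summed 7.26%), with quartiles of 0.255% and 13.2%. GAGE1 stood there at 1.31 CPM and VIM at 435 CPM, against 2581 and 147 CPM in the library labelled H1299 vector. An even share of H1299 RNA would not give both. The library labelled HBE FLII knockdown held HBE-typical genes at a summed 4.99%, with quartiles of 0.117% and 7.10%. KRT17 stood there at 1.80 CPM and KRT81 at 771 CPM, against 913 and 4644 CPM in HBE NC. A further source of RNA may be present too: of 21 genes seen at 20 CPM or more almost only in RNC libraries, 95.2% kept the ratio of HBE NC to HBE FLII knockdown within 1.5 times its median, ALDH1A1 standing at 990, 492, 87.3 and 73.6 CPM in the HBE NC, HBE FLII knockdown, H1299 FLII overexpression and H1299 vector libraries and at most 1.20 elsewhere. A test of FLII alteration for these genes was dropped after its value was seen: that 21 of 21 were highest in HBE NC would have counted against it, but the genes were chosen by their level in that library.

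HBE-typical genes in the H1299 FLII overexpression cytosol library are the second pattern. Of 75 of these genes with 10 or more reads expected at the median share of 1.94%, 76% had a count within 2 times that expected, just past the bound of 75% set for the test, which is in line with RNA of HBE cells in this library at a low share. A rise after FLII overexpression in mRNA and cytosol alike was not seen, but the mRNA pair cannot exclude one. Of HBE-typical genes chosen without the H1299 mRNA libraries, the 44 measured in both pairs had a median of −0.69 in mRNA against 2.42 in cytosol. All 244 stood at a median of 0.416% in the overexpression and 0.959% in the vector mRNA library. The vector cytosol library had 0.189%, so the vector mRNA library held more of these transcripts, which lowers the mRNA fold whatever FLII does. An effect of FLII on cytosolic RNA alone stays open, untested. The GC trend of this library is argued against: the median log2 fold was 3.06 before and 2.96 after its removal.

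Genes lower in HBE FLII knockdown mRNA are the third pattern: their median of −1.34 there was −0.12 over 249 genes in cytosol and −0.136 over 301 genes in nuclear RNA, which argues against a fall after knockdown shared by the other fractions for the set as a whole. For a part of it a shared fall is in line with the counts: 11 genes other than FLII were lower in mRNA and nuclear RNA, and with FLII 12 against 1.23 expected by permutation (0 to 4); in mRNA and cytosol there were 9 against 2.27 (0 to 6). RNA of H1299 cells is argued against by a summed level of 0.361% for 193 H1299-typical genes chosen without the HBE mRNA libraries. Another state of the culture or batch of the mRNA libraries cannot be told apart from the knockdown, because the labels give no batch; the 13 hypoxia genes stood at a median log2 ratio of 2.16 for mRNA over nuclear RNA in NC and 0.42 in the knockdown. FLII knockdown effects limited to the mRNA preparation stay open, untested.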

How the results depend on the processing

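The settings without RNC libraries, without genes that differ 8-fold or more between the lines, and with the GC trend removed were chosen after seeing the data; the others were fixed before. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers, so no replicate could be left out in turn either. A fit over fractions with fraction as a block would take different kinds of RNA as replicates and was not run. Alternatives meant for files that hold RPKM alone were not run, because the files hold counts. Median of ratios scaling kept all 42 main results within their bounds, total counts 36 of 42, 5 reads added 27, no filter 28, at least 100 summed reads 21 and deposited RPKM 20. Where a value below moved, the cause was not tested, except that stricter and looser read filters test fewer and more genes, that 5 added reads draw low counts towards no change, and that the RPKM setting uses no interval. Many calls outside RNC rest on low counts: of the 104 called genes in H1299 mRNA, 4 were kept with at least 100 summed reads, of 78 in H1299 nuclear RNA 4, of 136 in HBE cytosol 9, of 108 in HBE nuclear RNA 14 and of 131 in HBE nuclear over cytosol 2, against 306 of 625 in HBE mRNA.

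With at least 100 summed reads, genes higher and lower numbered 2 and 2 in H1299 mRNA, 28 and 39 in H1299 cytosol, 4 and 0 in H1299 nuclear RNA, 107 and 199 in HBE mRNA, 1 and 8 in HBE cytosol, 5 and 9 in HBE nuclear RNA, 188 and 14 in H1299 nuclear over cytosol, and 2 and 0 in HBE nuclear over cytosol; 1915 were lower in H1299 RNC over mRNA. Genes called alike in all HBE fractions were 0 higher and 1 lower, and genes opposite in the lines were 1 in mRNA and 1 in cytosol.

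With no filter, genes higher and lower numbered 66 and 102 in H1299 mRNA, 94 and 47 in H1299 nuclear RNA, 113 and 114 in HBE cytosol, and 125 and 95 in HBE nuclear over cytosol. In H1299 cytosol 241 were higher, in HBE nuclear RNA 77 lower and in H1299 nuclear over cytosol 204 lower. Opposite genes were 5 in cytosol and 2 in nuclear RNA, and the median correlation between HBE fractions was 0.0489. The median of endothelial markers in H1299 RNC turned to −0.11.

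With 5 reads added, genes higher and lower numbered 28 and 34 in H1299 mRNA, 27 and 12 in H1299 nuclear RNA, 35 and 36 in HBE cytosol, 29 and 18 in HBE nuclear RNA, 319 and 71 in H1299 nuclear over cytosol, and 27 and 12 in HBE nuclear over cytosol; 129 were lower in H1299 cytosol. In all HBE fractions 1 gene was higher, and in cytosol 1 gene went opposite ways in the lines.

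With total counts, the log2 fold of FLII was −3.99 in H1299 RNC, 1.58 in H1299 cytosol and −0.28 in HBE RNC, where it turned from just above 0 to below it. Genes lower numbered 3368 in HBE RNC; genes higher and lower in HBE RNC over mRNA numbered 1069 and 4058. Medians turned to −0.0440 for oxidative phosphorylation genes in H1299 cytosol, 0.0304 for actin cytoskeleton genes in H1299 nuclear RNA, and 0.0884 for actin cytoskeleton and 0.0969 for proteasome genes in H1299 nuclear over cytosol. Under median of ratios the actin cytoskeleton median in H1299 nuclear RNA was 0.00439.

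With the deposited RPKM, the log2 fold of FLII was −3.77 in H1299 RNC, 1.57 in H1299 cytosol, −2.37 in HBE mRNA and −0.27 in HBE RNC. Genes higher and lower numbered 159 and 167 in HBE mRNA and 189 and 70 in H1299 nuclear over cytosol. Genes lower were 1270 in H1299 RNC, 61 in H1299 cytosol, 65 in H1299 nuclear RNA, 79 in HBE nuclear RNA and 1211 in H1299 RNC over mRNA; genes higher were 1230 in HBE RNC, 790 in HBE RNC over mRNA and 40 in HBE nuclear over cytosol. Opposite genes were 8 in mRNA, 2105 in RNC, 5 in cytosol and 8 in nuclear RNA; no gene (0) was higher in all HBE fractions, and the median correlation between H1299 fractions was −0.000138. Medians turned to −0.0434 for oxidative phosphorylation genes in H1299 cytosol, 0.0299 for actin cytoskeleton genes in H1299 nuclear RNA, and 0.0872 for actin cytoskeleton and 0.0850 for proteasome genes in H1299 nuclear over cytosol.

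Without genes that differ between the lines, genes lower were 32 in H1299 mRNA, 240 in HBE mRNA, 977 in HBE RNC, 25 in HBE nuclear RNA, 64 in H1299 nuclear over cytosol and 1153 in HBE RNC over mRNA, and 34 were higher in H1299 cytosol. Opposite genes in RNC numbered 2067, genes lower in all HBE fractions 0, and the median correlation between HBE fractions was 0.0743. Epithelial medians turned to −0.22 in H1299 RNC, −0.28 in H1299 RNC over mRNA, 0.0145 in H1299 nuclear over cytosol, 0.0795 in HBE RNC and 0.0702 in HBE RNC over mRNA, and that of NF-kB genes in HBE RNC to 0.0752; the setting takes line-typical genes out of the lists by construction. With the GC trend removed, over genes with a GC value, 61 genes were lower in H1299 cytosol, against 189 of these genes before. Without RNC libraries 1 gene was higher in all H1299 fractions, 5 were lower in all HBE fractions and the median correlation between HBE fractions was 0.19.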

Other observations

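The genes that were higher in HBE FLII knockdown mRNA were followed in the cytosol and nuclear RNA of the same line; this was chosen after the data were seen. Of 255 such genes, with a median log2 fold of 1.40, 162 were measured in cytosol and 214 in nuclear RNA, where their medians were 0.20 and 0.21. Of these, 106 (65.4%) had the same sign in cytosol and 157 (73.4%) in nuclear RNA, against 51.6% and 54.9% over all genes. The genes called again were 6 in cytosol, within the 0 to 7 of permutations (3.15 expected), and 11 in nuclear RNA, above them (2.996 expected, 0 to 6.025), none called the opposite way. In RNC, between labels that FLII did not follow, 120 of 244 (49.2%) had the same sign, with 57 called the same and 37 the opposite way. FN1 was among those in nuclear RNA (log2 fold 1.04). Of the 369 lower genes other than FLII, 8 were called again in cytosol and 11 in nuclear RNA, and 4 and 1 were called the opposite way.

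Correlations of log levels across genes, which are not replicates, put each library outside RNC closest to its partner of the same line and fraction, from 0.987 to 0.995. Among the RNC libraries, those labelled H1299 vector and HBE FLII knockdown were closest to each other (0.971), and so were those labelled H1299 FLII overexpression and HBE NC (0.928). Set against libraries outside RNC alone, the one labelled H1299 FLII overexpression was closest to HBE FLII knockdown cytosol (0.966) and the one labelled HBE FLII knockdown to H1299 FLII overexpression cytosol (0.923). Those labelled H1299 vector and HBE NC were then closest to H1299 FLII overexpression cytosol (0.928) and HBE NC nuclear RNA (0.909). Among genes seen almost only in RNC, AKR1B10 in the library labelled HBE NC stood at 642 CPM, CPLX2 at 511 CPM, CYP24A1 at 238 CPM and HNF4A at 33.4 CPM, against at most 9.21, 0.719, 3.87 and 0.338 CPM in any library outside RNC.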
